A study of Mus musculus with 10 samples.

How the data were processed

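Genomic DNA of mouse proximal colon organoids was measured by exome sequencing. The labels describe 10 cultures of C57BL/6 background. In 3 of them Cre had switched on 1 BrafV600E allele, and these were cultured for 5 months and then grown in Base medium for 3 weeks. The other 7 were empty-vector cultures, of which 3 had been cultured for 5 months, 2 for 2 months, 1 for 12 months and 1 for 14 months. These were then grown in full medium for 3 weeks. Groups and culture numbers were taken from the sample titles. The 12-month and 14-month cultures form 1 group of long-term empty-vector cultures.

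Per the labels' protocols, TruSeq libraries were sequenced as paired ends on Illumina HiSeq instruments. The submitters' processing notes name the genome builds mm10 and GRCm38. The aligner, the variant caller, its filters, the statistical test and the culture that served as comparator for each list are not given in the sources used here. The values are those of 1 deposited table with 163 listed mutations in 5 of the 10 cultures. Each mutation has a chromosome, a base position, the reference and variant base, a gene symbol, a coding consequence, a mark for genes of the COSMIC cancer catalogue and a p-value. The p-value is the one the authors deposited for each mutation, and it was used to rank and filter mutations and, on the -log10 scale, to compare the support of groups of calls. It exceeded 0.05 for 2 listed mutations, Skint7 (0.0699) and Sorl1 (0.103), both in the 14-month culture. The table holds neither read depths nor shares of mutant reads, so the depth behind each mutation is unknown and the planned comparison of mutant read shares, as well as the filters at fixed mutant read shares, could not be run. All 163 listed mutations change the protein, so the planned share of protein-changing mutations was not computed and the truncating share was used instead. The 2-month and 5-month empty-vector cultures have no list in the table used here, and 5 cultures therefore entered no comparison.

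Gene symbols were matched to RefSeq genes of assembly GRCm38.p6, through older symbols for 4 mutations. Of the 163 positions, 162 lay inside the gene that the table names, on the same chromosome. The symbol Mrgpra6, of 1 mutation, had no match among 21896 protein-coding genes. No exon annotation or genome sequence was used, so positions were not assigned to exons, codons or sequence contexts. Substitutions were collapsed to the pyrimidine of the base pair, so that C-to-A includes G-to-T. Truncating mutations are frameshift and stop-gain mutations.

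The culture was the replicate. Means of the 3 BrafV600E cultures and the 2 long-term empty-vector cultures were compared with a two-sided exact permutation test over the 10 splits, whose smallest possible p is 0.1. Shares of mutations were also pooled within a group and compared with two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over the 5 shares tested. The COSMIC-marked share, the receptor-gene share and the median p-value were added after the data were seen. Fisher's test counts mutations and leaves out the spread between cultures. Counts have exact Poisson 95% intervals and shares exact Clopper-Pearson 95% intervals, which cover counting error only. The deposited names of equally numbered cultures share a prefix, BRAF1 or BRAF3, and nothing in the labels states whether it marks the same mouse. The series design calls the long-term cultures biological replicates, and for the BrafV600E cultures nothing says that they came from separate mice. Permutation p-values over cultures therefore measure only the spread between these cultures. P-values of tests that count mutations or calls do not include that spread. Tables of substitution classes were tested with 100000 permutations, and these tests were not part of the plan. In simulated lists of the same sizes, Fisher's test called 5.1% of pairs with equal shares of 0.3. These lists were drawn without spread between cultures, so this rate does not cover false calls that such spread can give.

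Before the data were examined, 10 gene lists were fixed (Wnt pathway; MAPK and receptor tyrosine kinases; PI3K and mTOR; TGF-beta and BMP; p53, DNA damage and cell cycle; DNA repair and proofreading; chromatin and DNA methylation; colorectal cancer drivers; colon stem and differentiation genes; long genes often listed as passengers), together with the groups, the tests and the rule for the genes named. The rule names every listed gene in a fixed list other than the passenger list, every gene listed in 2 or more cultures and every truncating mutation, which gave 19 genes. Other genes named in the text were chosen after their values were seen. The list test had been planned against coding length. Coding lengths were not used here, so the number of listed mutations per list was tested against the list's share of the 21896 genes with a two-sided exact binomial test, a choice made after the data were seen. This background favours lists of long genes, and genomic span, the alternative, includes introns. Random draws of genes, 10000 in number, gave the number of recurrent genes that chance gives.

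Settings chosen beforehand were substitutions only, removal of positions shared by cultures, protein-changing mutations only, leaving out each culture, and a replicate block on culture numbers 1 and 3. Filters at a p of 0.001 and of 1e-05, removal of olfactory and vomeronasal receptor genes, 1 call per gene and culture, another month count and a background of genomic span were added after the data were seen. Python 3.11.15, scipy 1.17.1, statsmodels 0.14.6, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.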

Results

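Organoids grown from the proximal colon of mice with a silent, Cre-activable BrafV600E allele were sequenced to ask which coding mutations accompany the switched-on oncogene and growth without stem-cell niche factors, and which appear during long culture without the oncogene. BrafV600E is an activating change in a kinase of the MAPK pathway. Base medium is the culture medium without the niche factors, in which the BrafV600E organoids had spent 3 weeks after 5 months of culture. Mutation lists covered 3 BrafV600E cultures in Base medium, numbered 1 to 3, and 2 empty-vector cultures in full medium, number 1 after 12 months and number 3 after 14 months. The lists held 163 mutations in 156 genes, of which 151 were missense, 8 frameshift and 4 stop-gain. Among the 8 frameshifts, 7 were deletions and 1 was an insertion. Read depth was unknown. The number of cultures and the length of the lists set the precision. None of the lists named Braf (0 of 163 mutations), so they gave no check of the engineered allele.

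Mutations in Ctnnb1, which encodes beta-catenin, the transcriptional effector of Wnt signalling, were listed in 2 of the 3 BrafV600E cultures and in neither long-term empty-vector culture. No test was run on this number of cultures. The groups differ at once in oncogene, medium and months in culture, so no difference between them can be credited to the oncogene alone. Ctnnb1 lies on chromosome 9 from 120933400 to 120960507 (GRCm38). Culture 1 carried C120950624A and C120950630A, and culture 3 carried C120950618T, where each name gives the reference base, the GRCm38 position on chromosome 9 and the listed base. The 3 positions, all missense, fell within 13 bp of each other. The authors' p-values for these mutations were 3.82e-08, 1.49e-07 and 0.000173, respectively. Culture 2, which had been selected in the same medium, had no listed Ctnnb1 mutation. Its list held Ror1, a receptor for Wnt ligands, with a missense mutation at chromosome 4 position 100442129 and an authors' p of 2.2e-26.

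Genes that the authors marked as COSMIC cancer genes were listed in the BrafV600E cultures and not in the long-term empty-vector cultures. They accounted for 7 of 99 mutations (7.07%, exact 95% interval 2.89 to 14.0%) against 0 of 64 (exact 95% interval 0 to 5.60%). In culture 1, these were the 2 Ctnnb1 mutations, a frameshift in Picalm (chromosome 7, 90182306), which encodes a clathrin assembly protein, and a missense mutation in Stk11 (chromosome 10, 80129977), a tumour-suppressor kinase. In culture 3 they were Ctnnb1, Kmt2d (chromosome 15, 98839513), a histone methyltransferase, and Nutm1 (chromosome 2, 112250056), a gene known from fusions in carcinoma, which is named here after its value was seen. Culture 2 had 0 of 22. Fat4, in the fixed list of colorectal cancer drivers, was listed in the 14-month culture without the COSMIC mark. The count of 0 of 64 therefore rests on the authors' marking. Fisher's exact test on mutations gave p = 0.0431 and an adjusted p of 0.108 over 5 shares, so the difference did not pass the adjusted test. An exact permutation test on the culture shares (6.47% ± 6.45, SD, n = 3, against 0 in both empty-vector cultures) gave p = 0.4. Counting 1 call per gene and culture, which makes the close pair in Ctnnb1 1 call, left 6 of 96 against 0 of 63 (Fisher's exact p = 0.0819).

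Of 357 genes in the fixed pathway and cell-type lists, 8 were listed, with 8 mutations in the BrafV600E cultures and 2 in the long-term empty-vector cultures. The Wnt list (101 genes) had 4 mutations, 3 in Ctnnb1 and 1 in Ror1, where its share of gene number gave 0.752 (exact binomial p = 0.00718, adjusted p = 0.0239 over 10 lists). Colorectal cancer drivers also had 4, the 3 in Ctnnb1 and 1 in Fat4, against 0.261 (exact binomial adjusted p = 0.000756). Fat4, an atypical cadherin, carried its missense mutation in the 14-month culture at chromosome 3 position 39000150. Long genes often listed as passengers had 5 mutations against 0.350 (exact binomial adjusted p = 0.00031), in Lrp1, Xirp2, Ttn and Fat4, so that a list of long or repetitive genes passed the same test. Against genomic span, a rough background for exome calls because it includes introns, none of the 10 lists passed (exact binomial adjusted p = 0.0802 for both the Wnt list and the driver list). The Wnt list also missed the threshold with 1 call per gene and culture (3 calls, adjusted p = 0.127 by the exact binomial test) or without any 1 of the 3 BrafV600E cultures, and the driver list without culture 1. Across the alternatives to this test over both groups together, exact binomial adjusted p ranged from 0.00886 to 0.311 for the Wnt list and from 0.000271 to 0.0963 for the driver list. None of the lists differed between the groups: for the Wnt list, 4 of 99 against 0 of 64 gave a Fisher's exact p of 0.155.

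The remaining lists had at most 2 mutations and did not pass the test. The chromatin list had Kmt2d in BrafV600E culture 3 and a frameshift in Smarcc1, a subunit of a chromatin remodelling complex, in the 12-month culture (chromosome 9, 110196253). MAPK and receptor tyrosine kinase genes had 1, a missense mutation in the ephrin receptor Epha5 (chromosome 5, 84331764). PI3K and mTOR genes had 1, Stk11. Colon stem and differentiation genes had 1, a missense mutation in the Notch ligand Dll1 (chromosome 17, 15368681). Epha5, Stk11 and Dll1 were all in BrafV600E culture 1. TGF-beta and BMP genes, p53, DNA damage and cell cycle genes, and mismatch repair, base excision repair and proofreading genes had 0 of 163 mutations each, where gene number gave 0.231, 0.223 and 0.149, so that a count of 0 was the likeliest outcome for each.

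The lists held 12 truncating mutations in 11 genes, of which Picalm was COSMIC-marked and Dgkb was hit in both groups. BrafV600E culture 1 had Picalm and a stop-gain in B4gat1, a glycosyltransferase (chromosome 19, 5039325). Culture 2 had a frameshift in the serotonin receptor Htr1f (chromosome 16, 64926926). Culture 3 had frameshifts in Vmn2r43, a vomeronasal receptor, and Dgkb, and a stop-gain in Ankrd35 (chromosome 3, 96683408). In the 12-month culture, the folate carrier Slc19a1 (chromosome 10, 77038543) and Smarcc1 had frameshifts. The 14-month culture had frameshifts in Vmn2r33 and Mrgpra6 and stop-gains in Dgkb and Astn2 (chromosome 4, 66185455). The truncating share was 6 of 99 (6.06%, exact 95% interval 2.26 to 12.7%) in the BrafV600E cultures and 6 of 64 (9.38%, exact 95% interval 3.52 to 19.3%) in the long-term cultures. The difference was smaller than counting error (Fisher's exact p = 0.542, odds ratio 0.626 with a 95% interval of 0.159 to 2.46). All 3 BrafV600E shares lay below both long-term shares, with the smallest p the exact permutation test allows, 0.1.

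Apart from Ctnnb1, the genes listed in more than 1 culture were Pcdh10 and Dgkb. Pcdh10, a protocadherin, had missense mutations in BrafV600E culture 1 and in the 14-month culture, 65 bp apart at chromosome 3 positions 45380245 and 45380310. Dgkb, a diacylglycerol kinase, had a frameshift in BrafV600E culture 3 at chromosome 12 position 38630584 and a stop-gain in the 14-month culture at 38139425, 491159 bp away. No position was shared by any cultures (0 of 163). With genes drawn by number, 1.16% of 10000 draws had 3 or more recurrent genes, and with genes drawn by genomic span, introns included, 53.1% did, so that an excess over chance depends on the weighting. Leaving out BrafV600E culture 1, BrafV600E culture 3 or the 14-month culture left 1 recurrent gene in each case.

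The numbers of listed mutations overlapped between the groups. The BrafV600E cultures had 31, 22 and 46 (33.0 ± 12.1, SD, n = 3), with exact Poisson 95% intervals of 21.1 to 44.0, 13.8 to 33.3 and 33.7 to 61.4. The long-term empty-vector cultures had 24 and 40 (32.0 ± 11.3, SD, n = 2), with intervals of 15.4 to 35.7 and 28.6 to 54.5. The difference of 1 mutation was far below the spread between cultures (exact permutation p = 1.0). The direction of this difference turned when BrafV600E culture 3 or the 12-month culture was left out (-5.5 and -7 mutations). Divided by the 5, 12 or 14 months in culture before the last 3 weeks, the lists held 6.6 ± 2.42 mutations per month (SD, n = 3) in the BrafV600E cultures and 2.43 ± 0.606 (SD, n = 2) in the long-term cultures. Each BrafV600E culture, at 6.2, 4.4 and 9.2 per month, lay above both long-term cultures, at 2.0 and 2.86, and the exact permutation p was 0.2. These are not mutation rates, because the comparator of each list, and so the time over which mutations were counted, is unknown. The median of the authors' -log10 p was 7.09 ± 1.26 (SD, n = 3) against 4.32 ± 0.349 (SD, n = 2; exact permutation p = 0.2), a value that depends on read depth and on the share of mutant reads.

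**Figure D1:**
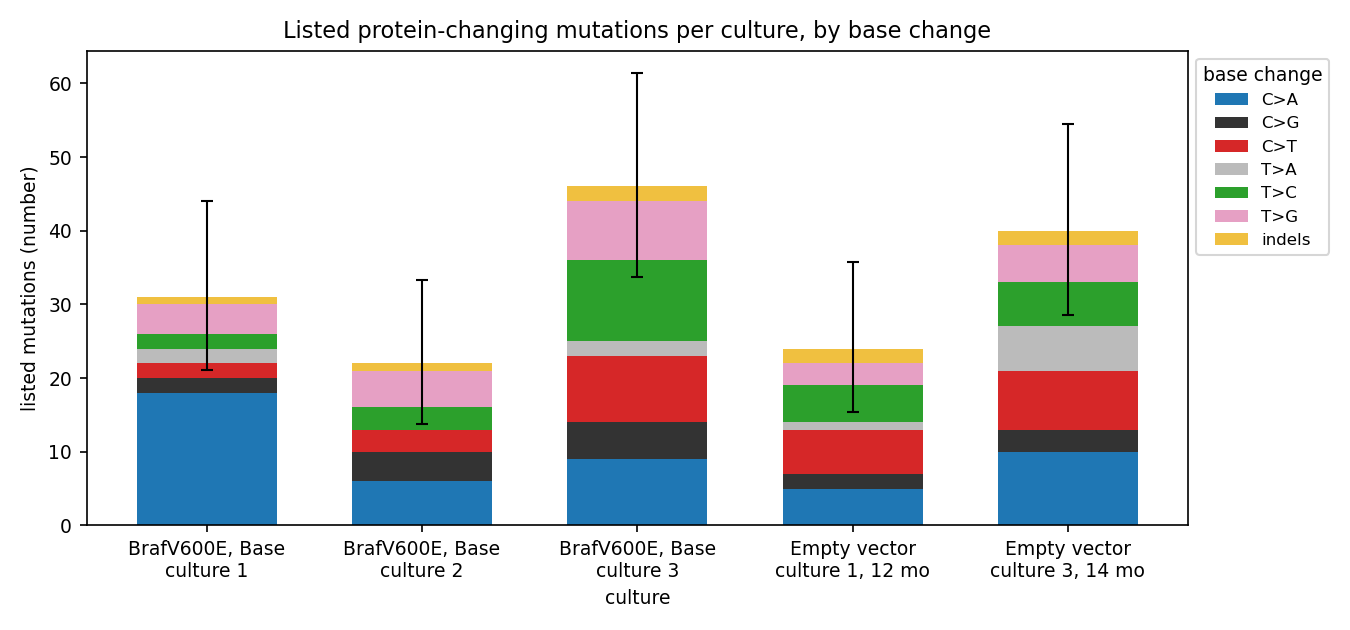
Stacked bars give the number of listed mutations in each of the 5 cultures, coloured by base change on the pyrimidine strand (C-to-A includes G-to-T), with exact Poisson 95% intervals (counting error only) on the totals. Totals run from 22 to 46 and overlap between the groups, and C-to-A changes take 18 of the 31 mutations of BrafV600E culture 1.

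Pooled over cultures, C-to-A changes were the most frequent substitution class in both groups, and their share was highest in BrafV600E culture 1. The lead was 15 against 14 C-to-T changes in the long-term group. C-to-A was not the leading class in BrafV600E culture 3, with 9 against 11 T-to-C changes, or in the 12-month culture, with 5 against 6 C-to-T changes. They made up 18 of 30 substitutions in culture 1 (60.0%, exact 95% interval 40.6 to 77.3%), 6 of 21 in culture 2 (28.6%) and 9 of 44 in culture 3 (20.5%). Long-term empty-vector cultures had 5 of 22 (22.7%) and 10 of 38 (26.3%). The pooled shares, 33 of 95 (34.7%) and 15 of 60 (25.0%), did not differ by Fisher's exact test (p = 0.217, odds ratio 1.59 with a 95% interval of 0.738 to 3.55), and culture shares of 36.3% ± 20.9 (SD, n = 3) and 24.5% ± 2.54 (SD, n = 2) gave an exact permutation p of 0.8. Without culture 1 the difference turned to -1.92 percentage points, and without culture 3 it was 22.1 points with a Fisher's exact p of 0.0177. Among the 3 BrafV600E cultures, C-to-A shares differed by more than counting error (permutation p = 0.00146, or 0.00568 with 1 call per gene and culture, which left 16 of 28 in culture 1). This test was not planned and covers the class in which culture 1 stood out, a choice that its p-value does not allow for. In culture 1, the 2 Ctnnb1 mutations and those in B4gat1, Dll1, Epha5 and Pcdh10 were C-to-A changes.

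C-to-T changes made up 14 of 95 substitutions (14.7%, exact 95% interval 8.30 to 23.5%) in the BrafV600E cultures and 14 of 60 (23.3%, exact 95% interval 13.4 to 36.0%) in the long-term cultures. The difference did not pass Fisher's exact test (p = 0.202, odds ratio 0.570 with a 95% interval of 0.229 to 1.42) or the exact permutation test on cultures (p = 0.2). The Ctnnb1 and Ankrd35 mutations of culture 3 were C-to-T changes. The whole table of 6 substitution classes did not differ between the groups (permutation p = 0.274) or across the 5 cultures (permutation p = 0.110).

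**Figure D2:**
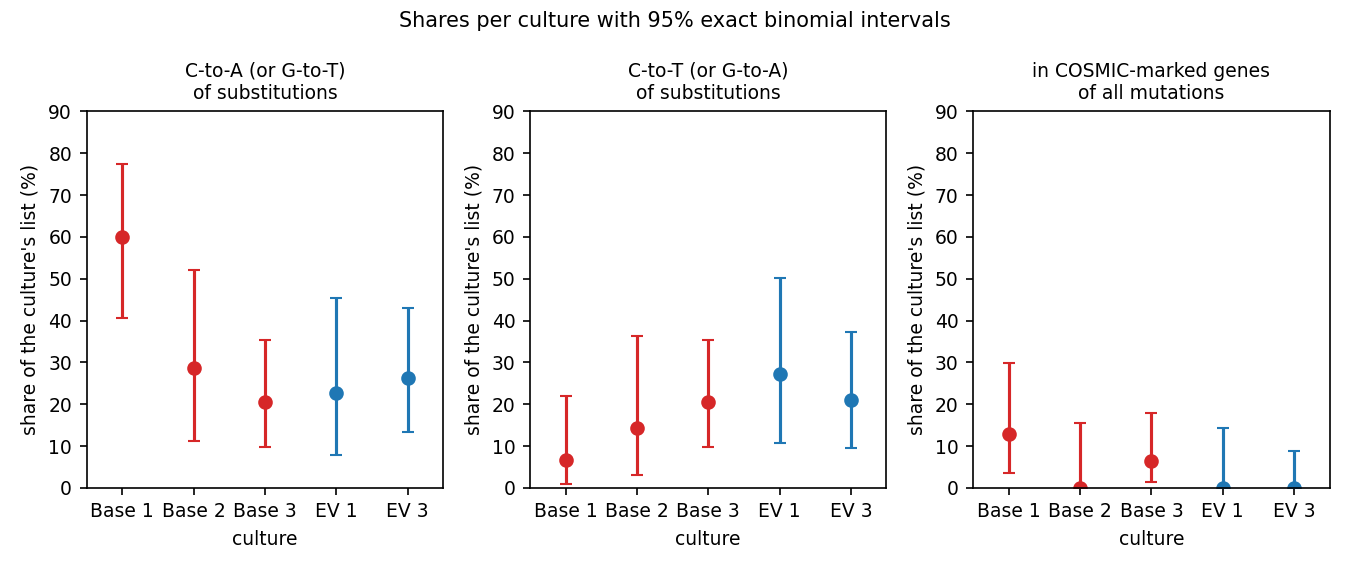
Points give each culture's share, in percent, of C-to-A substitutions (left), C-to-T substitutions (middle) and mutations in COSMIC-marked genes (right), with exact 95% binomial intervals; red marks the 3 BrafV600E cultures in Base medium (Base) and blue the long-term empty-vector cultures (EV). The C-to-A share of BrafV600E culture 1, 60.0%, stands above the other 4 cultures, and only BrafV600E cultures 1 and 3 have COSMIC-marked genes.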

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

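The alternatives listed as added in the methods were chosen after seeing the data. Removing shared positions and keeping protein-changing mutations removed nothing, so these settings test nothing. The COSMIC-marked difference (7.07 percentage points, Fisher's exact p = 0.0431) kept its direction under all alternatives. None of them could have turned it, because both long-term cultures had 0 marked calls and the alternatives only removed calls or cultures. The difference lost the unadjusted threshold with substitutions only (6.32), at a p of 0.001 or below (8.64), at 1e-05 or below (6.56), without receptor genes (7.95) and with 1 call per gene and culture (6.25). It also lost the threshold when BrafV600E culture 1 or either long-term culture was left out (4.41 to 9.09 over the 5 left-out cultures). Its Fisher's exact p ranged from 0.016 to 0.343. With the replicate block on cultures 1 and 3 it was 9.71, but 2 pairs cannot give a p under 0.5, so the block could hold no call. The labels do not say whether the shared names BRAF1 and BRAF3 mark the same mouse, and the block gave 6.5 more mutations per BrafV600E culture. Over left-out cultures, the difference in mutation number ran from -7 to 9 and the C-to-A difference from -1.92 to 22.1 points. The number of recurrent genes ran from 1 to 3 and was 1 at a p of 1e-05 or below. The gene left at that filter was Dgkb, hit in both groups. The Ctnnb1 call of BrafV600E culture 3 (authors' p of 0.000173) did not pass it, which left Ctnnb1 in culture 1 alone. The number of lists past the threshold, 3, ran from 1 to 3 and was 0 against genomic span, where counts stayed at 4 (Wnt), 4 (drivers) and 5 (passengers). Over left-out cultures, the Wnt list held 2 to 4 mutations and the driver list 2 to 4, and the Wnt list held 3 with 1 call per gene and culture. C-to-T, truncating and per-month differences kept their direction under every alternative run. For the per-month difference this says little, because mutation numbers were similar and every alternative divided the BrafV600E lists by fewer months. For C-to-T and truncating shares, Fisher's exact p stayed above 0.05, and the per-month difference had no test that can go below it. Causes were not tested beyond the smaller lists that these settings leave. Unknown depth limits whether an unlisted mutation was absent.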

Other observations

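All tests in this part were chosen after the results they measure had been seen.

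Olfactory and vomeronasal receptor genes, large families of sensory receptors, made up 29 of the 163 listed mutations. Long-term empty-vector cultures had 6 of 24 (25.0%) and 12 of 40 (30%), and the BrafV600E cultures had 2 of 31 (6.45%), 4 of 22 (18.2%) and 5 of 46 (10.9%). Pooled shares were 28.1% and 11.1% (Fisher's exact p = 0.00679, adjusted p = 0.0340 over 5 shares). The difference kept its direction under all alternatives run, but Fisher's exact p, which ranged from 0.00181 to 0.0987, rose to 0.0509 without BrafV600E culture 1 and to 0.0987 without the 14-month culture. The call with the smallest authors' p was B4gat1 in BrafV600E culture 1 (1.3e-21), Lrrc41 in culture 2 (7.96e-33), Olfr799 in culture 3 (9.04e-35), Olfr1248 in the 12-month culture (1.56e-15) and Pcdhga1 in the 14-month culture (2.03e-28).

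The first pattern is the excess of receptor genes in the long-term cultures. Random placement by gene number is argued against, since 1459 of 21896 genes (6.66%) belong to these families and 18 of 64 calls exceed that share (exact binomial p = 1.22e-07). In the BrafV600E cultures, 11 of 99 (11.1%) also lay above 6.66%, but the difference did not pass the test (exact binomial p = 0.101). By genomic span, introns included, these families hold 0.548%, which the shares of both groups exceed. No test was run against that background. Weak support is also argued against: in the long-term cultures, receptor-gene calls had a median authors' -log10 p 2.48 higher than other calls (permutation p = 0.0173). Reads placed on the wrong copy of a receptor gene may still account for it. Olfr823 and Olfr824, 14267 bp apart in the 14-month culture, carry the same A-to-T change with authors' p-values of 0.000111 and 0.000102. Their positions, 130112250 and 130126517, lie equally far from the starts of their genes, 130111841 and 130126108. That is the pattern that 1 event read on both copies would give, and both calls count in the 18 of 64. Theirs was the only pair within 50000 bp (1 pair), and sequences to compare copies were not used here. Grouping by chance cannot be told apart from a difference between the groups with 5 cultures (exact permutation p = 0.2). The groups differ at once in oncogene, medium and months in culture, which this design does not separate, and faster accumulation of mutations in silent genes stays untested.

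A second pattern is the C-to-A share of 60.0% in BrafV600E culture 1. Cultures 2 and 3 together had 15 of 65 (23.1%, exact 95% interval 13.5 to 35.2%). Their difference from the long-term cultures was -1.92 percentage points (95% Newcombe interval -16.9 to 12.9, counting error only), where culture 1 lay 35 points above them. This argues against a response of the full 35 points shared by the BrafV600E cultures. The excess was taken without an interval, although culture 1 was picked for its high share (exact 95% interval 40.6 to 77.3%). A smaller shared response stays open. Oxidation of guanine during library preparation, which gives C-to-A calls on few reads, could still account for it: C-to-A calls had a median authors' -log10 p 2.19 above the other substitutions (7.69 for 18 calls against 5.50 for 12), against the direction it needs, but the difference did not pass the test (permutation p = 0.275). A process particular to this culture stays open and was not tested.

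Another pattern is close pairs of calls in BrafV600E culture 1, C120950624A with C120950630A in Ctnnb1 (6 bp apart) and a pair of G-to-T changes in Lrp1, a lipoprotein receptor (2 bp apart, chromosome 10 positions 127595056 and 127595058). A candidate explanation is that each pair lies on the same molecules and is 1 event. The authors' p-values within a pair differed by 0.341 on the log10 scale on average, where random pairs of calls in this culture had a median gap of 4.64 (resampling p = 0.00334, one-sided). Equal depth at neighbouring bases also narrows the gap, and reads that carry both changes would decide it. Olfr153 in BrafV600E culture 3 had a pair 102 bp apart with a gap of 9.23.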
